A study of Rattus norvegicus with 8 samples.

How the data were processed

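Gene expression was measured in 2 lines of PC12 cells, a rat adrenal pheochromocytoma line that takes on neuronal features in response to nerve growth factor. PFR3K650E cells carry fibroblast growth factor receptor 3 (FGFR3) with the K650E mutation, which the series title ties to thanatophoric dysplasia type II, a lethal skeletal disorder, and PFR3 cells are the wild-type line. Per the labels, 3 clones of each line were induced for 24 h, equal amounts of their RNA were pooled, and 25 µg of total RNA was used to make labelled cRNA for Affymetrix Rat Genome U34 arrays (set A), which read 1 colour. The labels speak of 3 growths of each clone and of triplicate arrays, whereas 4 arrays were listed for each line. Which growth each array came from was not stated, so p-values measure the spread between these arrays, part of which may be technical.

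The values deposited by the authors were linear probe set intensities, and the software that made them was not given in the sources used here. The 2% trimmed mean was 501 on every array, so the intensities had been scaled to a common mean before deposit and were used as deposited. No detection calls were used here. Intensities under a floor of 15.3, the 20th percentile of all values, were raised to it, and log2 was taken. Of 8799 probe sets, 59 Affymetrix controls were left out, and the 5279 with an intensity above 57.8 (the 40th percentile) in at least 4 of the 8 arrays were tested, leaving out 3461. For arrays, the number of arrays limits the precision.

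Probe sets were named from the platform annotation, whose gene numbers were looked up in the names of the rat assembly GRCr8. Apart from the controls, 7006 probe sets had 1 gene symbol, 308 had several and 1426 had none. For 6994 the gene number was found, and 0 symbols differed. Probe sets with several symbols or none stayed in the test and were left unnamed. Among those tested, 4380 had 1 symbol, 209 had several and 690 had none, which gave 3175 genes. Fgfr3 itself was not analysed here, since 0 probe sets carried its name.

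PFR3K650E was compared with PFR3 with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), 2-sided, with Benjamini-Hochberg adjustment over the 5279 probe sets and an adjusted p threshold of 0.05. Differences are PFR3K650E minus PFR3, with the standard error (SE) of the fit. In all, 18 gene lists were fixed before the data were examined, and the 17 with at least 5 measured genes were tested with limma's camera (preset correlation 0.01), with 1 probe set per gene, the brightest over all 8 arrays. The list of glia and Schwann cell markers had 4 measured genes and was not tested. Camera with a correlation estimated from the arrays, and fry, were run beside it. Single measures per array were compared by exact permutation, 2-sided, where the smallest p that 4 against 4 arrays allow is 0.0286. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

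Genes were named by a rule fixed before the data were examined. It took the 8 genes with the smallest p in each direction if fewer than 3 probe sets passed, the 3 genes with the smallest p of each list, and the FGF receptors. Probe sets called without PFR3 replicate 1 or with array weights were added after their values were seen.

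The steps were tested on simulated data, with 200 of 5279 probe sets changed in each of 20 simulations. The noise was that of the fit to all 8 arrays, multiplied by a factor for each array (1.86 for PFR3 replicate 1). For PFR3K650E against PFR3 with all 8 arrays, 2.16% of 1.5-fold, 23.0% of 2-fold and 72.6% of 4-fold changes were recovered, with 2.15 false calls on average. These shares were, without PFR3 replicate 1, 3.61%, 30.4% and 76.5%, with 4.30 false calls. The noise of PFR3 replicate 1 entered both the fit and the factors, so the recovered shares may be too low. Without that array the median SE of the real fit was 0.235, against 0.293 with all 8 arrays. The simulated noise came from all 8 arrays in both cases. A shift of 0.5 log2 in a list of 28 genes was called in 20 of 20 simulations. That shift was larger than any list mean found with all 8 arrays (the largest was -0.41). The simulated noise was independent between probe sets, so the recovery of smaller shifts in lists whose genes move together was not tested.

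The alternatives were quantile normalization, a common median, other floors and filters, the replicate number as a block, no intensity trend, no moderation, the mean of a gene's probe sets, array weights, and leaving out each array in turn. Combinations of a second choice with the removal of PFR3 replicate 1, and a choice of each gene's probe set over the remaining 7 arrays, were added after seeing the data. That last choice was first made by mistake in the fits without an array, and was set back to the planned rule after results had been seen, which moved the lists called without PFR3 replicate 1 from 4 to 5.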

Results

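The data comprised 8 arrays, 4 of PFR3K650E cells and 4 of PFR3 cells, each reading 8799 probe sets after 24 h of induction. PFR3 replicate 1 stood apart from the other arrays. Its log2 signals correlated with theirs at r = 0.888 to 0.903 across probe sets, which are not independent replicates, against 0.956 to 0.972 for the 21 pairs of the other arrays. Its median signal was 134.7, while the other PFR3 arrays had 98.0 to 101.1 and the PFR3K650E arrays 84.7 to 101.4. The log2 ratio of 3' to 5' signal, a sign of RNA quality, was 0.67 ± 0.24 in PFR3K650E and 0.71 ± 0.22 in PFR3 cells for beta-actin (SD, n = 4, exact permutation p = 0.83), and 0.44 ± 0.14 and 0.52 ± 0.25 for GAPDH (exact permutation p = 0.6). PFR3 replicate 1 had the highest of both ratios, 0.98 for beta-actin (other arrays 0.37 to 0.90) and 0.84 for GAPDH (0.28 to 0.62).

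**Figure D1:**
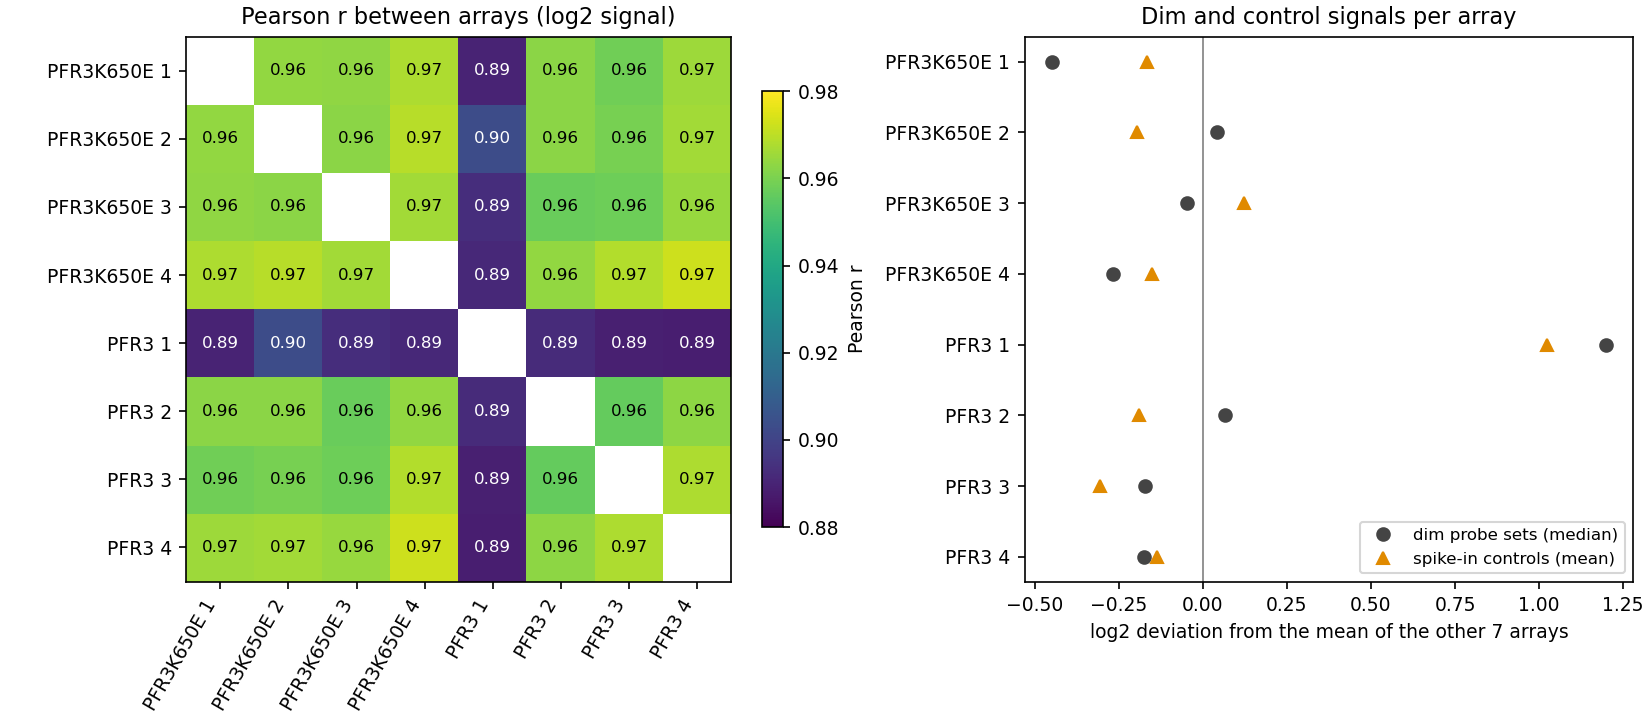
Left, Pearson r of log2 signal for each pair of the 8 arrays, by colour and number. Right, each array's log2 deviation from the mean of the other 7 for dim probe sets (circles, median) and spike-in controls (triangles, mean); PFR3 replicate 1 lies at 1.20 and 1.02, and the other arrays lie between -0.45 and 0.12.

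The comparison of PFR3K650E with PFR3 cells asked which transcripts differ between cells with the mutant and the wild-type receptor. Egr1, an immediate-early transcription factor, and Tubb2b, a beta-tubulin, had signals 2.95-fold and 2.86-fold higher in PFR3K650E cells (log2 differences 1.56 ± 0.25 and 1.51 ± 0.24, SE, 4 arrays per line). Cxcl14, a chemokine, was 2.0-fold lower (-1.0 ± 0.18), and Ccnd2, the cell cycle regulator cyclin D2, had dim signals of 29.7 to 71.4 in PFR3K650E arrays, near the floor, against 134.7 to 254.3 in PFR3 arrays (-2.11 ± 0.38). All 4 PFR3K650E arrays lay on 1 side of all 4 PFR3 arrays for each of these genes. The genes were picked by their small p in the same arrays, so this separation is no further evidence. None of them passed the adjusted threshold over all probe sets.

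With all 8 arrays, limma called 0 of 5279 probe sets, and the lowest adjusted p was 0.109, shared by Egr1, Tubb2b and the unnamed probe set rc_AI639312_at. At an unadjusted p under 0.05 there were 240 probe sets, 97 higher and 143 lower in PFR3K650E, where 264 are expected by chance. The test without moderation also called 0, with 271 at an unadjusted p under 0.05, and array weights called 9 (4 higher, 5 lower), with 394 (lowest adjusted p 0.112 and 0.00229). The lines did not overlap at 189 probe sets (3.58%), against a chance share of 2.86%.

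When PFR3 replicate 1 was left out, limma called 6 probe sets, and 360 had an unadjusted p under 0.05. Tubb2b rose by 1.53 ± 0.23, Egr1 by 1.40 ± 0.22, Hspb1, a small heat shock protein, by 0.78 ± 0.12, and Anxa2, a calcium-dependent membrane-binding protein, by 0.65 ± 0.11 (adjusted p = 0.0343, 0.0388, 0.0343 and 0.0476). Cxcl14 fell by 1.08 ± 0.16 (adjusted p = 0.0343) and rc_AI639312_at fell by 1.33 ± 0.16 (adjusted p = 0.0138). Most of these calls rested on the settings: over 27 settings Tubb2b, Egr1, Anxa2 and Cxcl14 passed in 3 and Hspb1 in 2, while rc_AI639312_at passed in 8 of 26. The log2 difference of Hspb1 was 0.30 ± 0.38 with all 8 arrays, since its signal was 24807 in PFR3 replicate 1 and 6176 to 6774 in the other PFR3 arrays. The 7 arrays separated by line at 395 probe sets (7.48%, chance share 5.71%). Array weights called 5 of these 6 probe sets (not Hspb1) and also Tesc, a calcium-binding protein (0.78 with all 8 arrays, unweighted), Ccnd2, Fosl2, a component of the AP-1 transcription factor (-2.18, with signals of 34 to 112.8 in PFR3K650E arrays, near the floor), and Aldh1a1, a retinaldehyde-oxidizing enzyme (-1.86).

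Further genes with small p in all 8 arrays were Lgals3, the lectin galectin-3 (0.95 ± 0.22), S100a4, a calcium-binding protein (0.80 ± 0.19), Thy1, a neuronal surface glycoprotein (0.71 ± 0.17), and Cga, the common alpha subunit of glycoprotein hormones (0.68 ± 0.17). Lower signals were found for Adora2a, an adenosine receptor (-0.78 ± 0.19), and, near the floor in PFR3K650E cells, for the neuropeptide gene Npy (-2.32 ± 0.53), Lep, which encodes leptin (-2.22 ± 0.55), and Ceacam4 (-2.57 ± 0.66). Their adjusted p lay between 0.445 and 0.694. Npy had signals of 130.1 to 188.2 in PFR3 arrays and of 15.3, the floor, to 71.2 in PFR3K650E arrays. Ceacam4 was at the floor in 2 PFR3K650E arrays, and its arrays overlapped between the lines. Probe sets of a gene did not all move together. The other 3 Egr1 probe sets gave 0.65, 0.49 and -0.12 (0.49, 0.95 and 0.13 without PFR3 replicate 1), the other Lep probe sets -0.06 and -0.24, the other Cga probe set -0.01, the other Fosl2 probe set -0.41, the other Thy1 probe set 0.35 and the other Cxcl14 probe set -0.82. The other 3 Hspb1 probe sets gave -0.10, 0.12 and 0.39 (-0.13, 0.41 and 0.45 without PFR3 replicate 1).

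**Figure D2:**
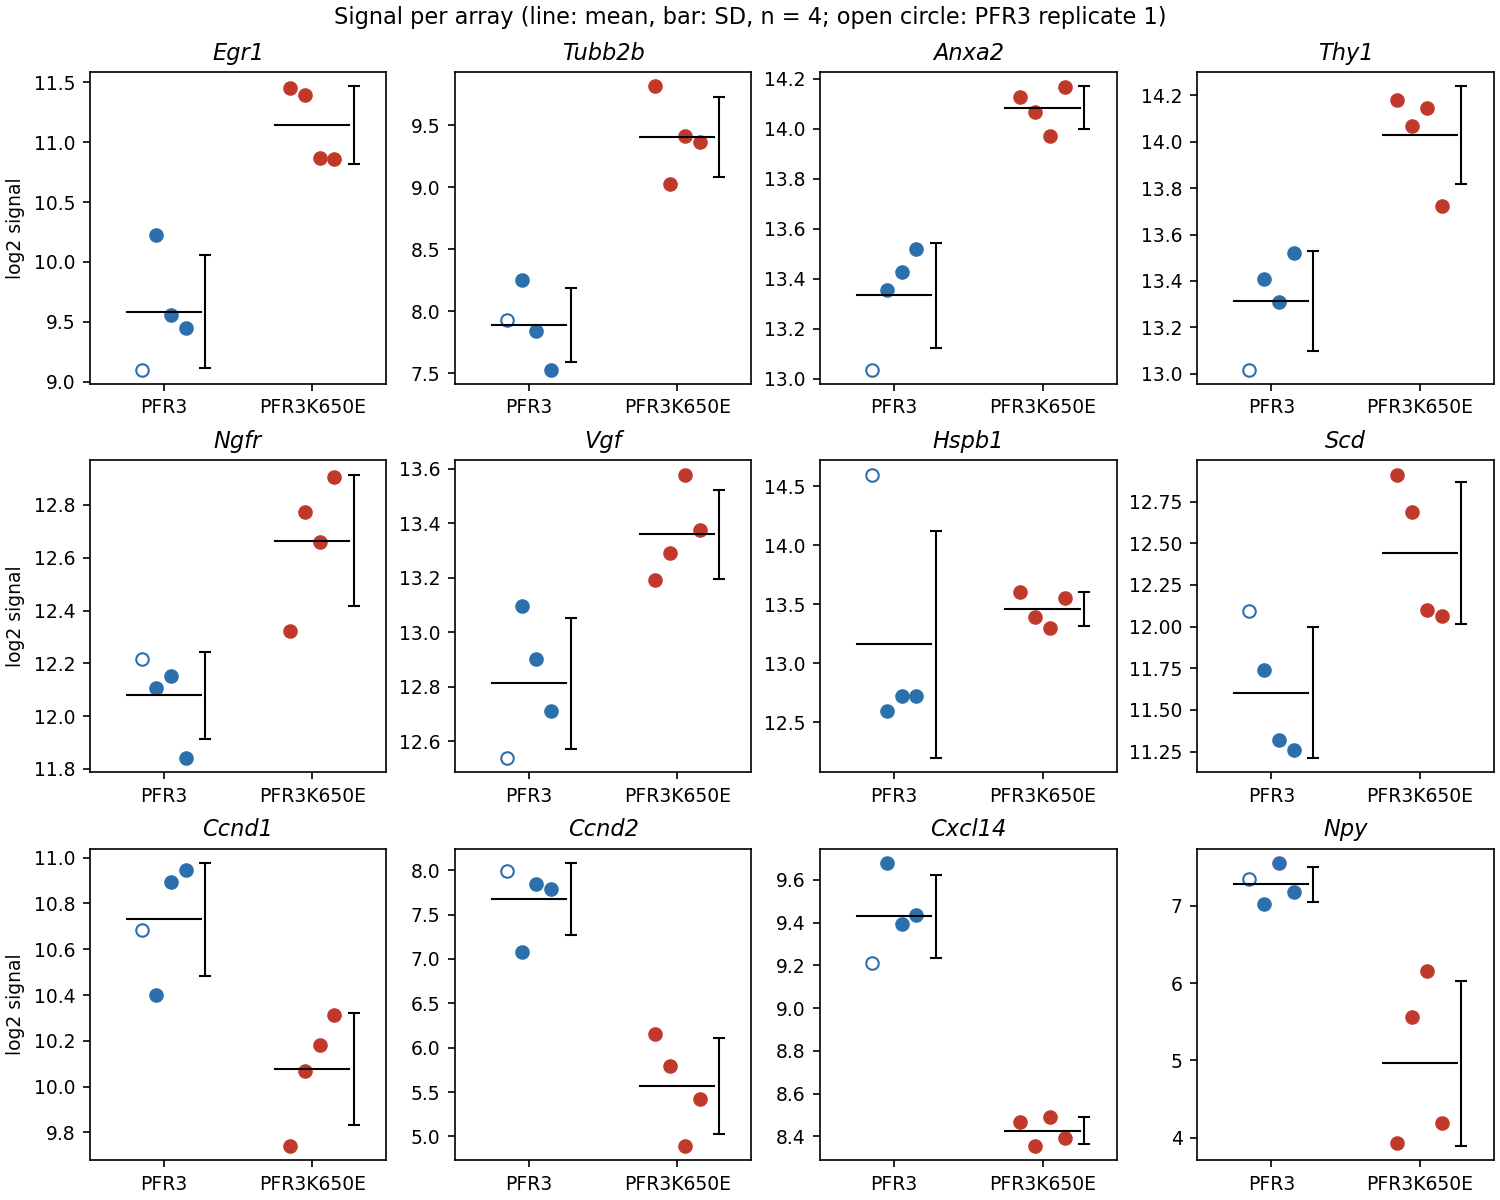
Log2 signal of 12 genes in each array, PFR3 in blue and PFR3K650E in red, with the mean (line) and SD (bar) of 4 arrays per line and PFR3 replicate 1 as an open circle. Egr1 lay at 11.14 ± 0.32 in PFR3K650E and 9.58 ± 0.47 in PFR3 cells, and Hspb1 in PFR3 replicate 1 lay at 14.60, above every other array.

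Of the 17 lists tested, camera with the preset correlation called 5 with all 8 arrays, 4 higher and 1 lower in PFR3K650E, and 5 without PFR3 replicate 1, of which 3 were called in both. With an estimated correlation, 0 were called in either fit, and fry called 1 in its directional test with all 8 arrays. Without PFR3 replicate 1, fry called the neuronal differentiation list (adjusted p = 0.0450, against 0.0591 with all 8 arrays). It also called the cyclin-dependent kinase inhibitor list there (fry adjusted p = 0.0407). Fry's mixed test takes changes in both directions. It called the secretory granule list with all 8 arrays (mixed fry adjusted p = 0.0314) and without PFR3 replicate 1 (0.00740). The cyclin-dependent kinase inhibitor list was called in both as well (mixed fry adjusted p = 0.00663 and 0.000328). The neuronal list was called only without PFR3 replicate 1 (mixed fry adjusted p = 0.139 and 0.000328).

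The neuronal differentiation list rose in PFR3K650E cells (28 genes, mean log2 difference 0.15, camera adjusted p = 0.00188). Its adjusted p = 0.101 with an estimated correlation, and 0.101 with quantile normalization, the highest over 25 settings (lowest 3.95e-05). Over all probe sets 0 members rose and 0 fell, and 4 rose adjusted over the list alone. These were Anxa2 (0.75 ± 0.15), Thy1, Ngfr, the low-affinity neurotrophin receptor (0.59 ± 0.17, its other probe set -0.08), and Vgf, a secreted precursor induced by nerve growth factor (0.55 ± 0.16). Gap43, a growth cone protein, had a difference of -0.01 ± 0.21, and 15 of the 28 differences were above 0. Members below 0 included the sodium channel gene Scn9a (-1.06 ± 0.55) and Stmn4 (-0.53 ± 0.45). The neurofilament genes Nefh (-0.17 ± 0.31) and Nefm (-0.13 ± 0.32) also lay below 0. The list's mean without PFR3 replicate 1 was 0.16 (adjusted p = 3.95e-05, and adjusted p = 0.0626 with an estimated correlation), 20 differences were above 0, 1 member (Anxa2) rose over all probe sets, and 5 rose adjusted over the list alone, the fifth being Prph, the neuronal intermediate filament peripherin (0.38 ± 0.12).

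The cholesterol and fatty acid synthesis list rose as well (19 genes, mean 0.21, 16 above 0, adjusted p = 0.000500; adjusted p = 0.172 with an estimated correlation). Scd, a fatty acid desaturase, had a difference of 0.84 ± 0.25, Fdps, the farnesyl diphosphate synthase, 0.50 ± 0.18, and Mvd, a decarboxylase of the mevalonate pathway, 0.43 ± 0.17. Over all probe sets 0 members passed, and 0 passed adjusted over the list alone. Its adjusted p ranged from 2.45e-05 to 0.0504 over 25 settings. The mean without PFR3 replicate 1 was 0.15 (adjusted p = 0.00259, and adjusted p = 0.283 with an estimated correlation), and 1 member rose adjusted over the list alone, Scd (1.0 ± 0.21).

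The list of cyclin-dependent kinase inhibitors and growth arrest genes fell (14 genes, mean -0.41, 3 above 0, adjusted p = 0.0260; adjusted p = 0.172 with an estimated correlation, and fry adjusted p = 0.0220). The 2 members that fell adjusted over the list alone were the D-type cyclins Ccnd2 and Ccnd1 (-0.65 ± 0.19), which promote passage through G1, and 0 members passed over all probe sets. The 4 Ccnd1 probe sets gave -0.50 to -0.73, of which 1 became -0.11 without PFR3 replicate 1. Cdkn1a, a kinase inhibitor, had a difference of 0.61 ± 0.27, or 0.38 ± 0.20 without PFR3 replicate 1, and its other probe set 0.19 ± 0.30, or 0.11 ± 0.29. The list's adjusted p was 0.0672 without PFR3K650E replicate 3 and 0.0783 without PFR3 replicate 4, and ranged from 0.00507 to 0.214 over 25 settings. It was 0.0424 without PFR3 replicate 1 (mean -0.32, adjusted p = 0.259 with an estimated correlation), or 0.0989 when each gene's probe set was chosen over those 7 arrays.

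The glycolysis and hypoxia list rose (20 genes, mean 0.11, 16 above 0, adjusted p = 0.0260; adjusted p = 0.174 with an estimated correlation). Its leading members were Slc16a3, a lactate transporter (0.69 ± 0.18), and Aldoc, an aldolase (0.39 ± 0.17), with 0 passing over all probe sets and 0 adjusted over the list alone. The list was not called without PFR3 replicate 1 (adjusted p = 0.148, mean 0.03, with Slc16a3 rising adjusted over the list alone) or without PFR3 replicate 4 (adjusted p = 0.0908), and its adjusted p ranged from 0.00185 to 0.525 over 25 settings. The endoplasmic reticulum stress and heat shock list rose (19 genes, mean 0.13, 15 above 0, adjusted p = 0.0476; adjusted p = 0.172 with an estimated correlation), led by Ddit3, a stress-induced transcription factor (0.47 ± 0.25). Its members passing were 0 over all probe sets and 0 adjusted over the list alone. Leaving out PFR3K650E replicate 1, 2 or 4, or any 1 PFR3 array, ended this call (adjusted p = 0.0528 to 0.111), and the range over 25 settings was 0.00676 to 0.419.

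Lists of immediate-early transcription factors and of ribosomal proteins also rose once PFR3 replicate 1 was left out. The immediate-early list (22 genes) had a mean of 0.09 and adjusted p = 0.0320 (adjusted p = 0.259 with an estimated correlation), 1 member, Egr1, rose over all probe sets, and adjusted over the list alone 1 rose and 1, Klf6, fell (-1.70 ± 0.48). With all 8 arrays its adjusted p was 0.366, its mean -0.00459 and its median -0.07, while camera gave it the direction up, with 0 members passing over all probe sets and 1, Egr1, rising adjusted over the list alone. Over 25 settings its adjusted p ranged from 0.00639 to 0.729. The ribosomal protein list (40 genes) had a mean of 0.15, 34 differences above 0 and adjusted p = 1.41e-05 (adjusted p = 0.344 with an estimated correlation, which was 0.34 between its genes), with 0 members passing over all probe sets and 0 adjusted over the list alone. With all 8 arrays its mean was 0.05 and its adjusted p = 0.0929, and it was called without PFR3K650E replicate 3 (adjusted p = 0.00632) and without PFR3K650E replicate 4 (adjusted p = 0.00343), with a range of 1.31e-05 to 0.962 over 25 settings.

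The remaining 10 lists were not called by camera in either fit. With all 8 arrays their mean log2 differences were -0.15 for feedback regulators of receptor tyrosine kinases (14 genes), -0.11 for secretory granule proteins (11), 0.08 for catecholamine synthesis (13), -0.10 for synaptic vesicle proteins (25), -0.02 for DNA replication (23), 0.01 for STAT and interferon-regulated genes (16), -0.12 for extracellular matrix (22), -0.19 for growth factors and receptors (33), -0.30 for voltage-gated channels (18) and -0.21 for fibroblast and muscle markers (9). Their adjusted p lay between 0.168 and 0.786, and 0 of their members passed over all probe sets. Adjusted over the list alone, Vgf rose and Npy fell in the secretory granule list, and 0 members passed in the other 9 lists. The secretory granule list had a median of 0.09, a negative mean and the camera direction up, and the DNA replication list had a median of 0.01, a negative mean and the direction up. In the fit without PFR3 replicate 1 the means were -0.16 for DNA replication (6 above 0, adjusted p = 0.0517), -0.09 for STAT and interferon-regulated genes, 0.00385 for extracellular matrix, -0.06 for growth factors and receptors and 0.06 for fibroblast and muscle markers (adjusted p = 0.649 to 0.955 for these 4). There, Rgs4, a brake on G protein signalling, fell adjusted over the feedback list alone and Ngfr rose adjusted over the growth factor list alone.

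**Figure D3:**
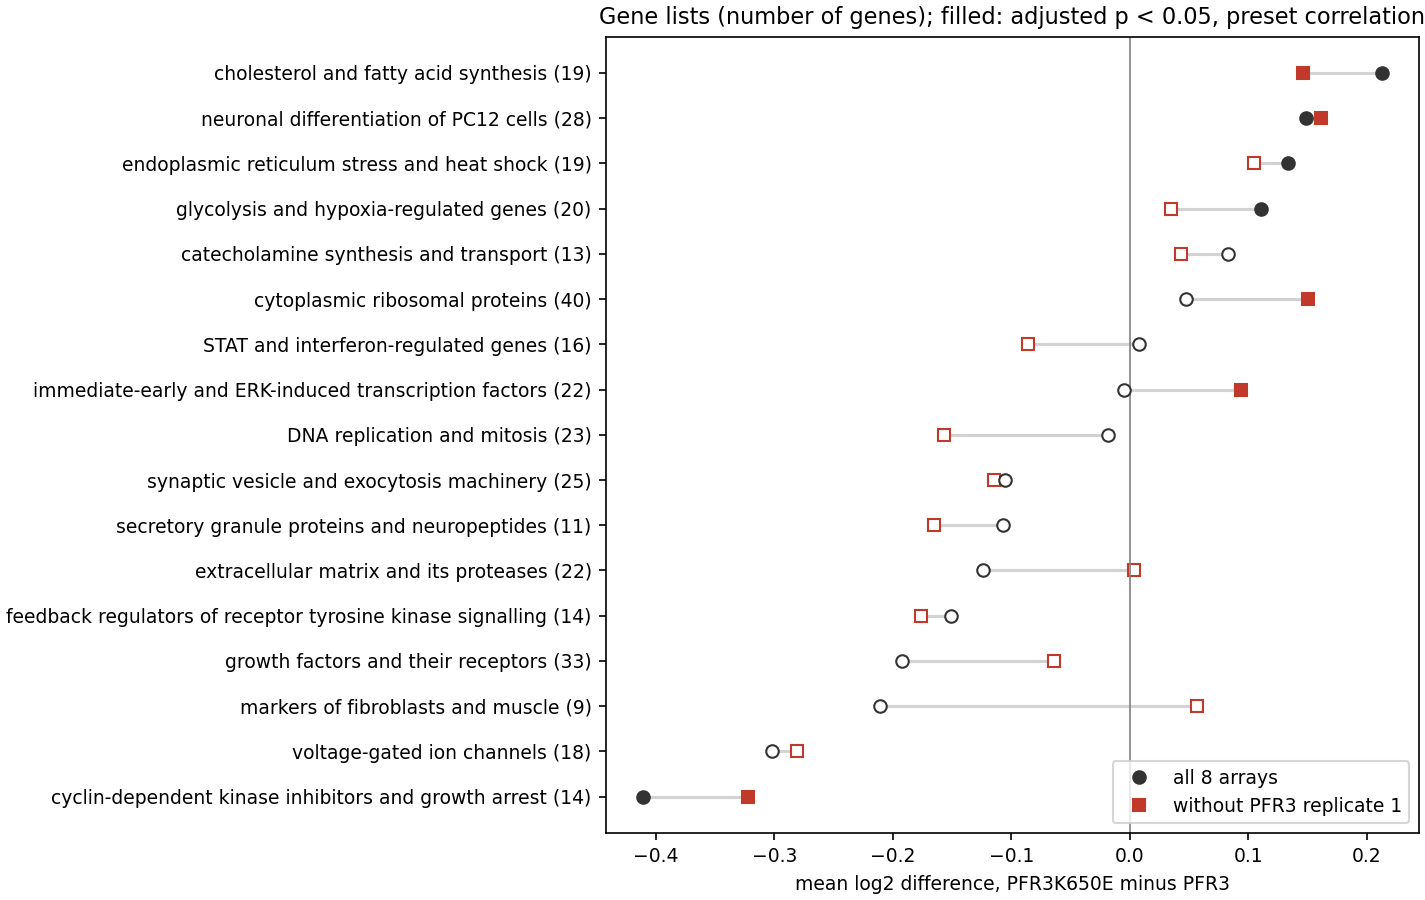
Mean log2 difference, PFR3K650E minus PFR3, of 17 gene lists with all 8 arrays (circles) and without PFR3 replicate 1 (squares), filled where camera with the preset correlation gave an adjusted p under 0.05. The neuronal differentiation (0.15 and 0.16), cholesterol and fatty acid synthesis (0.21 and 0.15) and cyclin-dependent kinase inhibitor lists (-0.41 and -0.32) are filled in both.

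Among the FGF receptors, Fgfr4 had a difference of -0.69 ± 0.29, Fgfr1 of 0.22 ± 0.25 and Fgfr2 of -0.24 ± 0.69, or 0.37 ± 0.59 without PFR3 replicate 1 and 0.11 without PFR3K650E replicate 2. A second Fgfr1 probe set gave 1.5 ± 0.45 and a second Fgfr4 probe set -0.33 ± 0.35. Adjusted p for these 5 probe sets lay between 0.866 and 0.976.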

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

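The tests of background and scaling, of the lists without PFR3 replicate 1, of each other array held out and of the cell markers as a set were chosen after the result was seen.

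Of 144 groups of 4 values examined, 11 held 1 array far from the other 3, where chance gives about 1 in 20 groups, and 7 of the 11 were PFR3 replicate 1. In that array the median signal was 134.7, the mean correlation with the other arrays 0.892 and the mean log2 spike-in signal 11.17, against 98.0 to 101.1, 0.951 to 0.955 and 10.01 to 10.15 in the other PFR3 arrays. Its log2 signals of Hspb1 (14.60) and Tesc (10.17) lay above those of the other PFR3 arrays, and those of Pfkp (8.95) and Rpl24 (12.92) lay below. The other values were the spike-in signal of PFR3K650E replicate 3 (10.38), Fosl2 in PFR3K650E replicate 1 (6.82), Lep in PFR3K650E replicate 2 (5.90) and Ddc in PFR3K650E replicate 4 (9.28).

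PFR3 replicate 1 was noisier than any other array, at 1.86 times the median array. Weak sample signal over an even background, scaled up to the common mean, may account for the raised dim probe sets (median log2 deviation 1.2, other arrays -0.45 to 0.07). Background and scaling without noise do not give the 116 moderately expressed probe sets that lay over 4-fold below the other arrays (1 to 17 in those). Another 30 lay over 4-fold above (0 to 2 in those). The test took no account of noise scaled up with a weak signal, so it cannot exclude weak signal for these. A large share of RNA of glia, fibroblasts or muscle is argued against, since the highest of their markers that were dim elsewhere reached 249 (Dcn, 11.6 elsewhere), under the bound of 701 set beforehand, but a small share stays open: the median log2 deviation of all 63 marker probe sets was 0.98, against 0.46 on average in random probe sets of the same signal (0.38% of 10000 sets as high), while 6 of them lay over 4-fold above the other arrays, against 6.77 on average in the random sets (68.9% as high). A PFR3K650E array under a PFR3 name stays open: the array lay nearer the PFR3K650E mean at 52.2% of 360 probe sets (95% exact interval 46.9 to 57.5%), but at only 1 (Hspb1) of the 6 called without it, and held-out PFR3K650E arrays gave 41.3 to 60.3% and held-out PFR3 arrays 40.7 to 59.3%, so that the share did not separate the lines. Its 3' to 5' ratios were the highest of the 8 arrays, so that degraded RNA stays open too, untested, and no biological explanation was tested.

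The neuronal differentiation list was higher in PFR3K650E, and neither PFR3 replicate 1 alone (adjusted p = 3.95e-05 without it) nor a shift of all probe sets of that mean signal (percentile 99.25 or above among 10000 random lists matched on it) accounts for that. The real split gave this list its largest distance from all genes (0.21, highest other split 0.17, 1 of 35 splits as large). Without PFR3 replicate 1 the distance was 0.205 (highest other split 0.183, 1 of 35). The catecholamine list, which was not called, was also largest in the real split. Since the neuronal list was picked out of 17 because it was called, chance stays open. Quantile normalization of all 8 arrays left the mean at 0.14, moved the median of all probe sets from -0.05 to 0.03 and ended the call (adjusted p = 0.101), whereas the call stood with a common median (0.30, adjusted p = 0.00507) and with quantile normalization without PFR3 replicate 1 (0.17, adjusted p = 0.00339), so that scaling stays open only in part. The call was also lost with an estimated correlation (adjusted p = 0.101), but the estimate was -0.02, so that genes moving together were not the reason, and the cause was not tested. A response to the mutant receptor remains a hypothesis that may account for the rest. Each line was read as pooled clones of that line, with induced cells only. Other differences between the clones of the lines therefore cannot be separated from such a response, and were not tested.

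The cholesterol and fatty acid list was higher in PFR3K650E both with and without PFR3 replicate 1 (adjusted p = 0.00259 without it), which argues against that array alone. Its mean lay at percentile 99.32 or above among matched random lists, which argues against a shift of probe sets of that signal. Chance stays open: with all 8 arrays the real split was the largest of 35 by a small margin (1 of 35 splits as large; distance from all genes 0.27, highest other split 0.26), without PFR3 replicate 1 it was not (0.19, highest other split 0.21), and the list was picked out of 17 because it was called. The call was lost with an estimated correlation (adjusted p = 0.172), but so were the calls of lists whose estimate was negative. The loss alone is thus no sign of genes moving together between arrays. The estimate between this list's genes was 0.11, so that such movement stays open. A response to the mutant receptor may contribute as a hypothesis. Here too, such a response cannot be separated from other differences between the pooled clones of the lines.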

How the results depend on the processing

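All combinations with the removal of PFR3 replicate 1 were chosen after seeing the data. The count of 0 changed probe sets held under the planned settings except 2: array weights called 9 (7 of them 2-fold) and leaving out PFR3 replicate 1 called 6 (4 of them 2-fold), so that leaving out 1 array gave 0 to 6 changed probe sets, 0 to 4 with a 2-fold change and 2 to 5 gene lists. The cause was not tested beyond the removal of the noisiest array. Low signal limits what can be measured for genes near the floor. In simulated cases 2-fold changes were recovered in 23.0%, a share that may be too low.

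Under a second choice beside the removal of PFR3 replicate 1, the changed probe sets were 1 with quantile normalization, 1 with a common median, 1 with no filter, 2 with no intensity trend, 1 with no moderation and 9 with array weights (2-fold: 1, 1, 1, 2, 1 and 6). The 1 probe set left under quantile normalization, a common median, no filter or no moderation was rc_AI639312_at, so that Tubb2b, Egr1, Anxa2, Cxcl14 and Hspb1 lost their calls there. Gene lists called were 5 (4 higher, 1 lower), against 2 with quantile normalization (1 higher, 1 lower), 2 with the filter at the 60th percentile, 2 without PFR3 replicate 4, 0 with an estimated correlation and 1 with fry. They were 3 without both PFR3 replicate 1 and the filter, and 4 without PFR3 replicate 1 when each gene's probe set was chosen over 7 arrays. A plain test without moderation has no list version and was not run for the lists. A common median moved the median log2 difference of all probe sets from -0.05 to 0.14.

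With the replicate number as a block, 0 probe sets were called (194 at an unadjusted p under 0.05) and 5 lists, or 0 and 1 without PFR3 replicate 1. The numbers did not pair the arrays: deviations of arrays with the same number correlated at -0.06 to 0.11, those with other numbers at -0.16 to 0.20, and 1 of 8 arrays correlated best with its own number.

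Among named genes, 12 values turned sign and 29 newly passed, and 1664 kept both direction and side. Fgfr2 (-0.24) became 0.39 with array weights, 0.11 without PFR3K650E replicate 2 and 0.37 without PFR3 replicate 1 (-0.68 to 0.37 over leaving out 1 array); without that array it was 0.40 with quantile normalization, 0.44 with a common median, 0.47 with array weights, 0.44 with the block and 0.37 with no filter, no trend or no moderation. Dnajb1 (-0.27) became 0.018 with a common median and 0.036 with the block, and the DNA replication list became lower and was called, -0.13 with quantile normalization (adjusted p = 0.0351) and -0.15 with array weights (adjusted p = 0.0408), each without PFR3 replicate 1, 2 calls in 25 settings (adjusted p = 0.0351 to 0.986). The cause was not tested.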

Other observations

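The tests of other splits of the arrays and of the probe sets of 1 gene were set before their results were seen, apart from the latter, and the count at an unadjusted p, without PFR3 replicate 1, and the genes of the first paragraph were named by the rule fixed before the data were examined, except where stated.

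Within the lists that did not shift, some members differed in opposite directions, and none of them passed over all probe sets. In the synaptic vesicle list, Sv2b, a vesicle glycoprotein, had signals of 97.9 to 159.1 in PFR3K650E arrays and of 15.3, the floor, to 91.7 in PFR3 arrays, whereas the calcium sensors Syt9 (-0.85 ± 0.26) and Syt1 (-0.91 ± 0.39) were lower. In the secretory granule list, Scg3, a granin, was higher in all 4 PFR3K650E arrays (0.39 ± 0.16) and Npy was lower. Rgs4 was 1.87-fold lower (-0.91 ± 0.27) and Socs3, a feedback inhibitor of cytokine receptors, 2.03-fold lower (-1.02 ± 0.46). For both of these genes the arrays overlapped between the lines. The 3 probe sets of Ret, the receptor of the GDNF family, gave 0.51, 0.86 and 1.24, the last 2 of which were looked at after their values were seen. Ddc, the decarboxylase of dopamine synthesis, had a difference of 1.06 ± 0.51 that became 0.42 ± 0.17 without PFR3 replicate 1, where its signal was 79.1 against 396.0 to 558.9 in the other PFR3 arrays.

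Other splits of the arrays were counted for each total. With all 8 arrays the real split called 0 probe sets and the highest other split 1, and since all 35 splits reach 0, this count decides nothing about chance. The real split without PFR3 replicate 1 called 6 probe sets and the highest other split 2 (1 of 35 splits as many). Chance stays open for that count, since the splits were run under the main setting alone and removing any other array gave 0 calls. The 6 became 1 with quantile normalization and 0 with the replicate block, but 9 with array weights. Chance cannot be excluded for the 360 probe sets at an unadjusted p under 0.05, which 5 of 35 splits reached (550 in the highest other split). For the 5 lists called with all 8 arrays the highest other split had 4 (1 of 35 splits as many), a margin too small to exclude chance. For the 5 lists without PFR3 replicate 1 chance cannot be excluded, with 5 in another split (2 of 35). The 240 probe sets at an unadjusted p under 0.05 were reached by 10 of 35 splits, with 436 in the highest other split, so chance cannot be excluded there. Of the lists called, chance cannot be excluded without PFR3 replicate 1 for the immediate-early list (distance from all genes 0.14, highest other split 0.23; 9 of 35 splits as large) and the ribosomal protein list (0.19, highest other split 0.30; 10 of 35), nor with all 8 arrays for the glycolysis and hypoxia list (0.17, highest other split 0.18; 2 of 35). Chance stays open for the cyclin-dependent kinase inhibitor list, where the real split was the largest with all 8 arrays (0.35, highest other split 0.30) but not without PFR3 replicate 1 (0.28, highest other split 0.29; 2 of 35), and for the endoplasmic reticulum stress list, since the margin over the highest other split was small without PFR3 replicate 1 (0.20 and 0.17 with all 8 arrays, 0.15 and 0.14 without it). The catecholamine list, which was not called, was also largest in the real split (0.14, highest other split 0.13), so that this count alone sets no list apart.

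A difference between the lines that different probe sets of a gene share was tested as a hypothesis across 905 genes with at least 2 probe sets. The log2 differences of the 2 brightest probe sets correlated across genes at r = 0.252, but 11 of 35 splits gave as high a correlation (highest other 0.331). Without PFR3 replicate 1 the correlation was 0.289, and 2 of 35 splits gave as high a value (highest other 0.331). The real split was thus not the highest in either fit, the hypothesis was not borne out, and genes are not independent replicates here.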
